A study of Mus musculus with 6 samples.

How the data were processed

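Messenger RNA was sequenced from 3T3-L1 cells, a mouse fibroblast line that can be differentiated into adipocytes, in 3 control libraries and 3 libraries of cells given chronic intermittent hypoxia (CIH), meaning repeated spells of low oxygen. Per the labels' protocols, cells were grown with 10% serum, induced with insulin and then kept in medium with 0.1 µM insulin until day 8. Directional libraries were made from 1.3 µg of total RNA. Oxygen levels, cycle times and the time of harvest are not given in the sources used here. The labels name no separate cultures, so p-values measure the spread between these libraries, which may be technical.

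All values were deposited as FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), a unit read from the values themselves because the file headers give only sample names. The submitters' processing notes list the GRCm38 build, featureCounts 1.5.0-p3 and DESeq 1.8.3 without saying what each was used for, and the aligner is not given in the sources used here. Replicates 1 and 2 of both groups are deposited as gene tables of 54532 genes. Replicate 3 of both groups is deposited as transcript tables of 50660 entries for 21950 gene IDs, and these entries were summed per gene. In the gene tables, FPKM multiplied by the gene's exon length came in whole steps: 98.4%, 98.6%, 98.4% and 98.5% of genes with fewer than 50 fragments lay within 0.05 of a whole fragment in control 1, control 2, CIH 1 and CIH 2 (10% by chance). The steps correspond to about 25700000, 28000000, 26200000 and 27400000 fragments in these libraries. Values of the transcript tables were fractional, so the depth of control 3 and CIH 3 is unknown. Transcript tables and gene tables were therefore processed separately, by steps that are not given for either kind, and levels are not comparable across the tables.

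Gene symbols, biotypes and coordinates came from GENCODE mouse release 21 (GRCm38). Of 21769 gene IDs present in all 6 files, 21753 had a symbol and 16 had no entry in the reference. The 32763 genes listed only in the gene tables were left out of the comparisons of all 6 libraries. Values were taken as log2(FPKM + 1), so that fold changes are on that scale and understate the change of low genes. The 10976 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 (R 4.3.3; empirical Bayes with a trend) and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Tables and figures were made with Python 3.11.15.

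The planned design held the group alone, fitted to all 6 libraries. A count test had been planned first, with limma on log2 values as its stated replacement for files without counts, and the replacement was used. After the values were seen, more fits were added: a term for the kind of table (the processing term), a fit of replicates 1 and 2 alone (2 against 2), and the interaction between group and kind of table. The replicate 3 pair alone has 1 library per group, so it has no p-value. For the same reason the interaction test takes its spread from the gene tables alone. Its calls therefore assume that control 3 and CIH 3 vary no more than those. Gene lists of the replicate 3 pair were placed as percentiles of the list median among 10000 random lists of the same size, matched on mean expression in 20 bins. Random lists hold unrelated genes, so a list of genes that vary together can reach an extreme percentile whatever the cause. Most lists lay at or near either end, so these percentiles describe the pair and are no test of CIH.

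The groups share replicate numbers 1 to 3. Deviations from the group means correlated across genes between same-numbered libraries at 0.529, 0.587 and 0.581, all over 0.1, so by the rule set for this check the numbers pair the samples. The pairing comes from these correlations, not from the labels. Control 1 with CIH 2 (0.568) and control 2 with CIH 1 (0.567) correlated as highly, so that the structure separates replicate 3 from replicates 1 and 2. The fit with a replicate block was an alternative. Control 1 and control 2 differed by more than sampling noise, with a mean chi-square of 14.1 over 13894 genes of at least 20 fragments (1 without a difference), as did CIH 1 and CIH 2 (9.59), so each was kept as a library of its own.

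The 31 gene lists, the rule for named genes, the main test and most alternatives were fixed before the data were examined. Lists with at least 3 tested members (28) were tested with camera of limma at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. Named genes were the 12 with the largest upward and the 12 with the largest downward change among called genes whose 3 CIH libraries lay on the same side of the 3 controls. This part was applied to the fit with the processing term after its values were seen, because the planned fit called 0 genes; 16 genes were eligible upward and 35 downward, with clone-style, microRNA, small nucleolar and pseudogene names left out. Named as well were up to 4 members of each list with the smallest p in the planned fit, and in any case Hif1a, Epas1, Vegfa, Slc2a1, Adipoq, Lep, Pparg, Fasn, Slc2a4 and Ucp1.

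Alternatives were scaling by library totals, by the median of ratios, by the upper quartile and after leaving out the 20 most abundant and the mitochondrial-encoded genes, quantile normalization, voom on the recovered fragments of replicates 1 and 2 (chosen after the data were seen), a pseudocount of 0.1, other filters and thresholds, the replicate block and each library left out in turn. The fits were tested on simulated data (10817 genes, 50 changed per fold). These kept the real genes' means, but shuffled the spreads of the gene tables among genes and widened them for the transcript tables. Simulated changes were placed only on genes above a minimum mean level, so the recovery rates do not cover low genes. Each simulated change was the same in both kinds of table. The rates of fits that use both kinds therefore do not hold for genes whose change differed between them. Of genes changed 2-fold, the planned fit recovered 0%, the replicate block 60%, the processing term 88% and replicates 1 and 2 alone 96%. Of genes changed 8-fold, these fits recovered 34%, 90%, 96% and 100%.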

Results

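Gene expression was measured in 6 libraries of 3T3-L1 cells given a protocol of adipocyte differentiation, 3 control and 3 CIH. The series names a control group and a model group and compares their messenger RNA. Control 1, control 2, CIH 1 and CIH 2 came as gene tables with total FPKM of 321390, 319607, 361231 and 340564. Control 3 and CIH 3 came as transcript tables with totals of 850766 and 550322. Mitochondrial-encoded genes took 14.2%, 11.2% and 43.7% of the total in control 1, 2 and 3, and 15.5%, 16.3% and 22.4% in CIH 1, 2 and 3. These shares are not comparable between the kinds of table. The gene mt-Atp8 alone was 136373 FPKM in control 3 and 32434 in CIH 3. It was 5.52 and 7.88 in control 1 and 2 and 6.37 and 6.97 in CIH 1 and 2. Across the 10976 tested genes, which are not independent replicates, log2 values correlated at 0.996 between control 1 and 2 and at 0.997 between CIH 1 and 2. Control 3 and CIH 3 correlated at 0.756 with each other, control 3 at 0.802 with control 1, and CIH 3 at 0.616 with CIH 1. The first principal component held 76.9% of the variance and parted the transcript tables from the gene tables, so replicates 1 and 2 and the replicate 3 pair are kept apart below, and a fold given without its libraries is that of replicates 1 and 2.

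**Figure D1:**
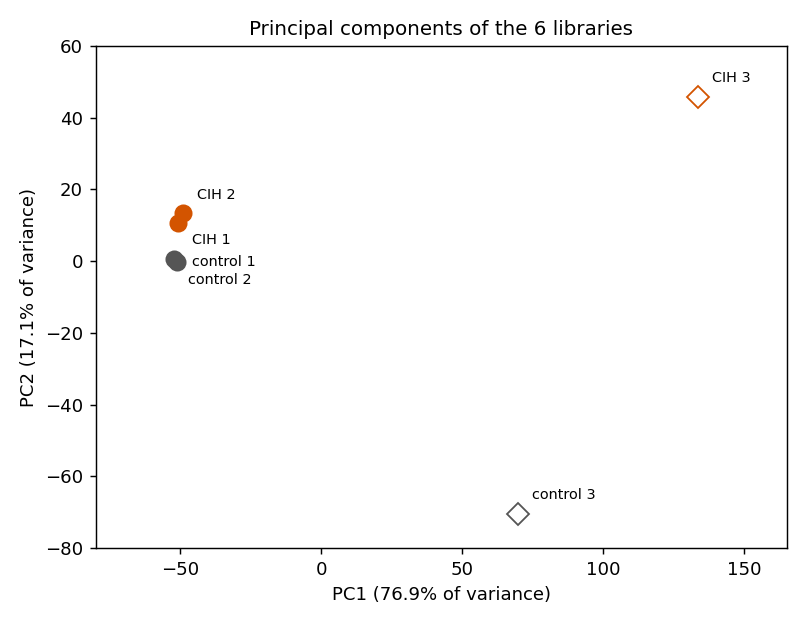
Each point is a library placed by its first (76.9% of variance) and second (17.1%) principal component of log2(FPKM + 1) over 10976 genes; grey is control, orange is CIH, filled circles are gene tables and open diamonds are transcript tables. The 4 gene tables lie together at the left, and control 3 and CIH 3 lie apart from them and from each other.

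The comparison asked which messenger RNAs differ between cells given CIH and control cells. In replicates 1 and 2, most genes known as targets of hypoxia-inducible factors and most genes of fatty acid and cholesterol synthesis were lower in CIH, while most genes of the cell cycle and several chemokines were higher. With an estimated correlation, camera called none of these lists in replicates 1 and 2 (adjusted p = 0.252, 0.252, 0.494 and 0.252). In the planned fit it then called hypoxia-inducible targets and fatty acid synthesis (adjusted p = 0.049 and 0.0207) but not cholesterol synthesis or the cell cycle (adjusted p = 0.0778 for both). With a term for the kind of table it called none of these lists (camera adjusted p = 0.196, 0.18, 0.383 and 0.383). Bnip3, a mitophagy receptor induced by low oxygen, went from 433 ± 55.7 FPKM (SD, n = 2) in control 1 and 2 to 96.5 ± 10.3 (SD, n = 2) in CIH 1 and 2, and was 316 in control 3 and 39.1 in CIH 3. Scd2, a fatty acid desaturase, went from 803 ± 26.5 to 202 ± 3.89 FPKM (SD, n = 2) and was 483 in control 3 and 100.4 in CIH 3. Mcm5, a subunit of the replicative helicase, went from 2.03 ± 0.394 to 9.28 ± 0.393 FPKM (SD, n = 2) and was 0.824 in control 3 and 4.94 in CIH 3. Ccl2, a chemokine that attracts monocytes, went from 1.12 ± 0.113 to 6.09 ± 0.647 FPKM (SD, n = 2) and was 3.28 in control 3 and 13.4 in CIH 3.

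By the planned limma fit of all 6 libraries, 0 of 10976 genes were called, with 490 at an unadjusted p under 0.05 (549 expected by chance) and a lowest adjusted p of 0.614. With a replicate block, limma also called 0 genes, with 1123 at an unadjusted p under 0.05. In 870 genes the 3 CIH libraries lay above the 3 controls and in 767 below, 14.9% of genes where chance gives 10%. That 10% holds for exchangeable libraries, which the 2 kinds of table are not: exchanging the names within the replicate 3, 2 or 1 pair gave 9.93%, 1.24% and 1.47%. With the processing term, limma called 63 genes, 20 higher and 43 lower, with 2052 at an unadjusted p under 0.05. That count was 0 with a replicate block and 0 when control 1, control 2, CIH 1 or CIH 2 was left out. It was 4274 without control 3 and 4271 without CIH 3. In those 2 fits the processing term absorbs the 1 transcript table left, so they come down to replicates 1 and 2 alone. The 63 calls became 0 after scaling by totals, 118 higher and 152 lower by the median of ratios, and 92 higher and 91 lower by the upper quartile. Replicates 1 and 2 alone gave 4292 calls, 1995 higher and 2297 lower, among them all 63, with 1865 calls without CIH 1 and 2316 without CIH 2. There, scaling by totals gave 1424 higher and 2952 lower, and upper-quartile scaling 2610 higher and 1843 lower.

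Of the 1995 genes that rose in replicates 1 and 2, 638 were at least 2-fold higher in CIH 3 than in control 3 (436 expected for independent lists) and 260 at least 2-fold lower (235 expected). Of the 2297 that fell, 448 were at least 2-fold lower (270 expected) and 400 at least 2-fold higher (502 expected). Log2 changes of the 2 kinds of table correlated across genes at r = 0.175 (rho = 0.0989). Contrasts of the gene tables that do not part the groups correlated with the replicate 3 pair about as much in size, at −0.171 (control 1 and CIH 1 against control 2 and CIH 2) and 0.151 (control 1 and CIH 2 against control 2 and CIH 1). The median change of all genes was −0.01 in replicates 1 and 2 and 0.26 in the replicate 3 pair. It moved to −0.12 and 0.86 with scaling by totals and to 0.00 and −0.13 by the median of ratios, so list medians of the replicate 3 pair are given relative to that of all genes. Percentiles use expression-matched random lists instead, whose typical median in that pair differed between lists. It was −0.63 for the nuclear-encoded respiratory chain, −0.66 for ribosomal proteins and 0.54 for the cell cycle.

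The 12 largest upward changes with the processing term included 3 chemokine genes. Cxcl1, a neutrophil attractant (chromosome 5, 90891241 to 90893115, GRCm38), rose 3.88-fold in replicates 1 and 2, from 0.242 ± 0.196 to 3.81 ± 0.551 FPKM (SD, n = 2). It was 2.37 in control 3 and 23.5 in CIH 3 (log2 change 2.26, SE 0.251, adjusted p = 0.0489). Ccl7 (chromosome 11, 82045712 to 82047525) rose 3.38-fold, from 3.07 ± 0.183 to 12.8 ± 1.03 FPKM (SD, n = 2). Its values were 3.43 and 17.7 in the replicate 3 pair (log2 change 1.86, SE 0.133, adjusted p = 0.0307). Its neighbour Ccl2 (chromosome 11, 82035571 to 82037453) rose 3.35-fold in replicates 1 and 2 and was 3.37-fold higher in the replicate 3 pair (adjusted p = 0.0309). Mcm5 (chromosome 8, 75109569 to 75128439) rose 3.41-fold (adjusted p = 0.0322), and Ube2c, which works with the anaphase-promoting complex, rose 2.81-fold from 2.31 to 8.30 FPKM (adjusted p = 0.0343). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose 3.51-fold from 4.11 ± 0.0618 to 17.0 ± 0.973 FPKM (SD, n = 2). Cpt1a was 14.3 in control 3 and 33.5 in CIH 3 (adjusted p = 0.0484). Igfbp7, a secreted growth factor binding protein, rose 2.71-fold from 72.6 ± 6.16 to 198.3 ± 7.32 FPKM (SD, n = 2; adjusted p = 0.0445). Junb, an AP-1 transcription factor, rose 3.15-fold (adjusted p = 0.0445). The other 4 were Clca3a1 (2.86-fold), Steap1 (3.23-fold), Pimreg (2.85-fold) and Map1a (2.68-fold), all at least 2.97-fold higher in the replicate 3 pair. The fit with the processing term assumes the same change in both kinds of table, and sizes differed for some genes. In log2 units, replicates 1 and 2 and the replicate 3 pair gave 1.96 and 2.86 for Cxcl1 and 1.81 and 1.17 for Cpt1a. Clca3a1 gave 1.52 and 2.31, while Mcm5 gave 1.77 and 1.70 and Ccl2 1.74 and 1.75.

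Downward, the 12 largest changes were led by Ghrh, which encodes growth hormone-releasing hormone (chromosome 2, 157329497 to 157347506). Its expression fell from 201.5 ± 7.45 to 0.251 ± 0.031 FPKM (SD, n = 2) in replicates 1 and 2, a 162-fold fall. Ghrh was 18.0 in control 3 and listed at 0 in CIH 3 (log2 change −6.31, SE 0.656, adjusted p = 0.0463). That pooled change lies between −7.34 in replicates 1 and 2 and −4.25 in the replicate 3 pair. Cyp2e1, a cytochrome P450, fell 7.31-fold from 9.14 ± 0.189 to 0.392 ± 0.148 FPKM (SD, n = 2) and was 6.80 and 0.0815 in the replicate 3 pair (adjusted p = 0.0268). Apoc3, an apolipoprotein, fell 7.19-fold in replicates 1 and 2 and was 6.33 in control 3 and listed at 0 in CIH 3 (adjusted p = 0.0268). Anxa8, an annexin, fell 8.60-fold (adjusted p = 0.0319), Klf15, a transcription factor of adipocytes, 4.17-fold (adjusted p = 0.0319), and Cyp2ab1 5.48-fold (adjusted p = 0.0361). Bnip3 (chromosome 7, 138890836 to 138909519) fell 4.45-fold (adjusted p = 0.0445), and Egln3, an oxygen-sensing prolyl hydroxylase (chromosome 12, 54178981 to 54203860), fell 4.01-fold from 125.2 ± 1.46 to 30.5 ± 0.427 FPKM (SD, n = 2; adjusted p = 0.0268). Lipid genes made up the other 4: Pnpla3 fell 4.77-fold (adjusted p = 0.0361), Scd2 3.96-fold (adjusted p = 0.0371), the nearby Scd3 4.31-fold (adjusted p = 0.0268) and Cyp51 3.45-fold (adjusted p = 0.0463). Scd2 and Scd3 are closely related paralogs, so fragments of either may be shared. Among these 12, log2 sizes in replicates 1 and 2 and in the replicate 3 pair also differed for Anxa8 (−3.10 and −2.23). They differed for Pnpla3 (−2.25 and −3.13) and Bnip3 (−2.15 and −2.98) too, and less for Cyp2e1 (−2.87 and −2.85).

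Of 21 tested targets of hypoxia-inducible factors outside glycolysis, 18 fell in replicates 1 and 2, 0 rose and 3 were not called (19 down and 1 up adjusted over the list alone; camera adjusted p = 3.27e-10, and adjusted p = 0.252 with an estimated correlation). Vegfa, the vascular endothelial growth factor (chromosome 17, 46016993 to 46032369), fell from 111.1 ± 10.7 to 43.2 ± 0.67 FPKM (SD, n = 2). Vegfa was 78.9 in control 3 and 28.8 in CIH 3 (log2 change −1.37, SE 0.130, adjusted p = 0.0426 with the processing term). Fam162a fell 1.94-fold in replicates 1 and 2 (adjusted p = 0.00412) and was 3.21-fold lower in the replicate 3 pair. Hilpda, a droplet protein induced by hypoxia, fell 2.10-fold (adjusted p = 0.00162) and was 15.5 in control 3 and 10.0 in CIH 3. For this list, camera gave adjusted p = 3.16e-15 in the planned fit (adjusted p = 0.049 with an estimated correlation). Its median change was −1.29 in replicates 1 and 2, and in the replicate 3 pair it lay at −0.85 relative to all genes, percentile 1.78 of random lists. Taken by itself that median was −0.59, and −0.00 with scaling by totals. Of the 21 members, 11 were lower in CIH in both kinds of table and 9 were higher in CIH 3 than in control 3. By the interaction test 12 were more positive and 5 more negative in replicate 3. Hif1a and Epas1, which encode the oxygen-regulated subunits of these factors, were not called (adjusted p = 0.215 and 0.341 with the processing term). Hif1a was 9.44 ± 1.75 and 12.3 ± 0.889 FPKM (SD, n = 2) in replicates 1 and 2, and 27.0 and 47.6 in the replicate 3 pair. Epas1 was 24.0 ± 0.308 and 21.5 ± 0.902 FPKM (SD, n = 2), and 55.5 and 25.5.

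Of 18 glycolytic genes, 14 fell in replicates 1 and 2, 2 rose and 2 were not called (14 and 2 adjusted over the list alone). Ldha, lactate dehydrogenase A, fell from 711 ± 9.7 to 326 ± 32 FPKM (SD, n = 2; adjusted p = 0.00362) and was 630.1 in control 3 and 88.0 in CIH 3. Pdk1, a kinase that holds back pyruvate oxidation, fell 4.98-fold (adjusted p = 0.000392), Pfkl 1.98-fold (adjusted p = 0.00299) and Gpi1 1.68-fold (adjusted p = 0.00491). These were 1.58-fold, 4.66-fold and 3.08-fold lower in the replicate 3 pair. Slc2a1, the basal glucose transporter (chromosome 4, 119108711 to 119137983), went opposite ways in the tables. It fell 4.39-fold from 81.1 ± 4.24 to 17.7 ± 1.19 FPKM (SD, n = 2; adjusted p = 0.000522) in replicates 1 and 2. Slc2a1 was 2.31-fold higher in CIH 3 (38.4) than in control 3 (16.1), and its adjusted p with the processing term was 0.471. For glycolysis, camera gave adjusted p = 2.2e-10 in the planned fit (adjusted p = 0.0287 with an estimated correlation) and 8.4e-05 in replicates 1 and 2 (adjusted p = 0.516 with an estimated correlation). The list median was −0.71 in replicates 1 and 2, and −1.59 relative to all genes in the replicate 3 pair, percentile 0.26.

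**Figure D2:**
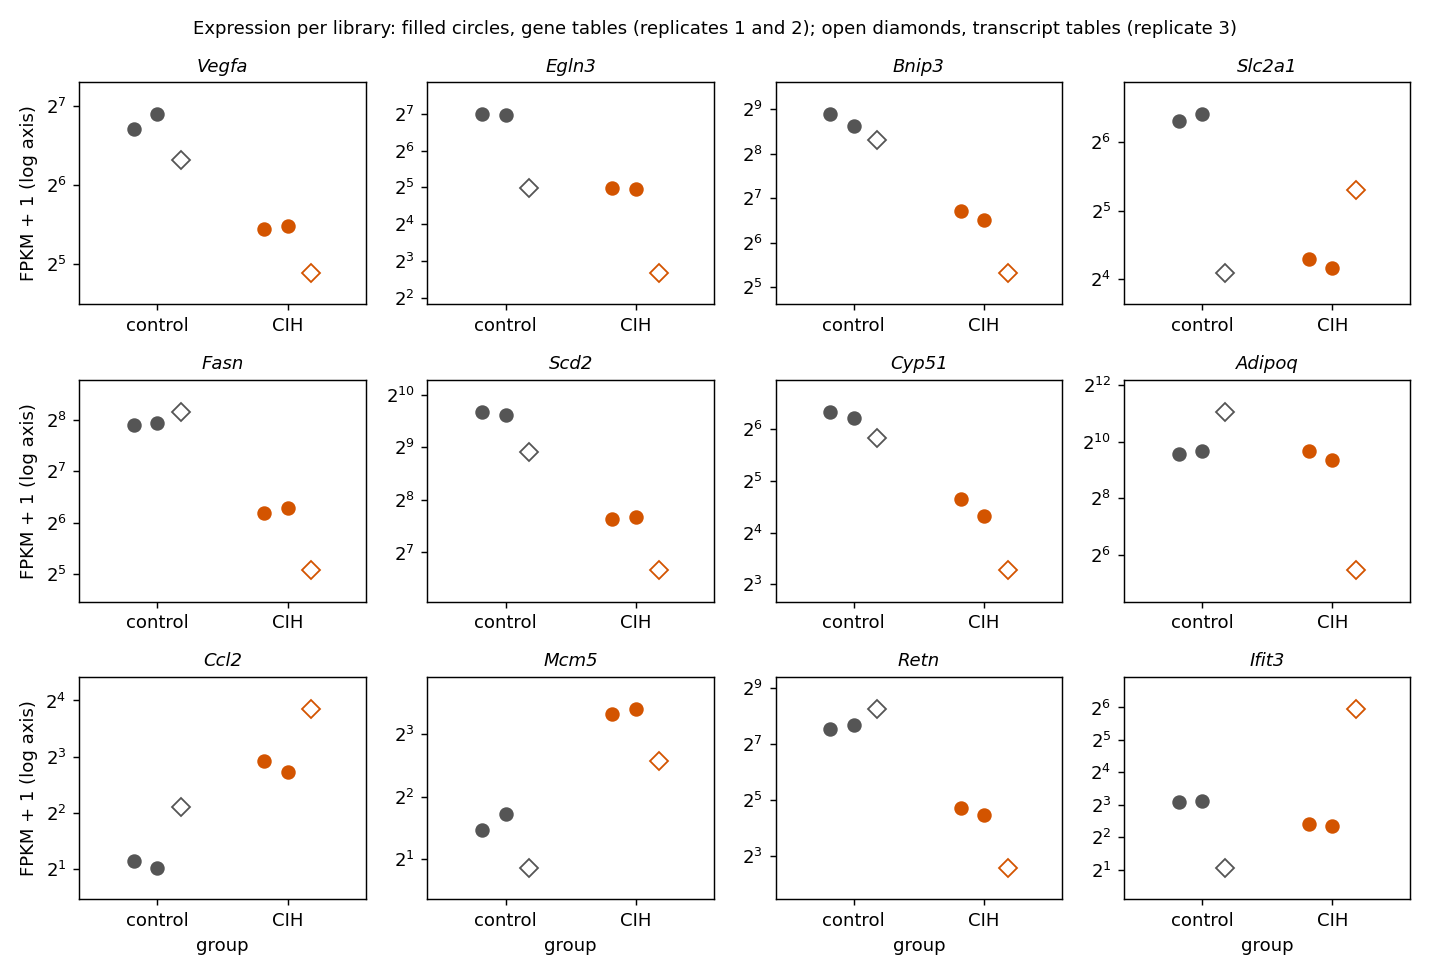
Each panel plots FPKM + 1 on a log axis for a named gene in the 3 control (grey) and 3 CIH (orange) libraries, with filled circles for gene tables and open diamonds for transcript tables. Vegfa, Egln3, Bnip3, Fasn, Scd2, Cyp51 and Retn are lower and Ccl2 and Mcm5 higher in CIH within both kinds of table, while Slc2a1 and Ifit3 go opposite ways and Adipoq differs in the replicate 3 pair (2156 and 42.7).

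Genes of fatty acid synthesis fell in replicates 1 and 2 for 14 of 18 members, with 1 higher and 3 not called (14 and 1 adjusted over the list alone). Fasn, fatty acid synthase (chromosome 11, 120805846 to 120824547), fell from 242 ± 4.08 to 74.3 ± 3.31 FPKM (SD, n = 2; adjusted p = 0.000685) and was 287 in control 3 and 32.7 in CIH 3 (adjusted p = 0.0768 with the processing term). Pnpla3, a lipase-like protein of lipid droplets, fell from 9.22 ± 0.336 to 1.14 ± 0.0465 FPKM (SD, n = 2) and was 8.03 and 0.0294 in the replicate 3 pair. Fads2, a desaturase of polyunsaturated fatty acids, fell 3.27-fold (adjusted p = 0.000549) and was 1.59-fold lower in the replicate 3 pair. For fatty acid synthesis, camera gave adjusted p = 7.78e-17 in the planned fit (adjusted p = 0.0207 with an estimated correlation) and 3.62e-06 in replicates 1 and 2 (adjusted p = 0.252 with an estimated correlation). The list median was −0.95 in replicates 1 and 2, and −2.09 relative to all genes in the replicate 3 pair, percentile 0.

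Cholesterol synthesis genes fell for 15 of 23 members in replicates 1 and 2, with 0 higher and 8 not called (16 and 0 adjusted over the list alone). Insig1, a sterol-regulated retention protein, fell 2.81-fold (adjusted p = 0.000837), Sqle, squalene epoxidase, 2.53-fold (adjusted p = 0.00112), and Fdft1, squalene synthase, 1.62-fold (adjusted p = 0.00495). In the replicate 3 pair these were 4.98-fold, 3.04-fold and 3.10-fold lower. Cyp51, lanosterol demethylase, went from 76.5 ± 4.92 to 21.6 ± 3.6 FPKM (SD, n = 2) and was 55.5 in control 3 and 8.67 in CIH 3. For cholesterol synthesis, camera gave adjusted p = 7.78e-17 in the planned fit (adjusted p = 0.0778 with an estimated correlation) and 3.62e-06 in replicates 1 and 2 (adjusted p = 0.494 with an estimated correlation). The list median was −0.56 in replicates 1 and 2 and −2.33 relative to all genes in the replicate 3 pair, percentile 0.

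Markers of white adipocytes split between the tables. In replicates 1 and 2, 11 of 22 fell, 2 rose and 9 were not called (11 and 3 adjusted over the list alone), with a median of −0.27. In the replicate 3 pair all 22 were at least 2-fold lower, with a median of −5.24 relative to all genes, percentile 0. By the interaction test, limma called all 22 as more negative in replicate 3. Adipoq, which encodes adiponectin, was 792 ± 41.5 and 730 ± 107 FPKM (SD, n = 2) in replicates 1 and 2 (adjusted p = 0.561), but 2156 in control 3 and 42.7 in CIH 3. Cfd, the serine protease adipsin, fell from 1114 ± 142 to 100.2 ± 18 FPKM (SD, n = 2; adjusted p = 0.000746), and Retn, which encodes resistin, from 193 ± 14 to 23.4 ± 2.86 FPKM (SD, n = 2; adjusted p = 0.000516). Retn and Cfd were 51.0-fold and 78.5-fold lower in the replicate 3 pair. Pparg, the nuclear receptor that drives adipocyte differentiation, fell 1.88-fold (adjusted p = 0.00383) and Slc2a4, the insulin-responsive glucose transporter, 3.68-fold (adjusted p = 0.000746). They were 6.90-fold and 36.8-fold lower in the replicate 3 pair. For white adipocyte markers, camera gave adjusted p = 3.41e-16 in the planned fit (adjusted p = 0.219 with an estimated correlation) and 0.00904 in replicates 1 and 2 (adjusted p = 0.574 with an estimated correlation). Lep, which encodes leptin, reached at most 0.217 FPKM and Ucp1, the uncoupling protein of brown fat, at most 0.119, below the filter.

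Adipokine genes fell for 10 of 14 members and rose for 2 in replicates 1 and 2 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00535, and adjusted p = 0.516 with an estimated correlation). Nampt fell 1.89-fold (adjusted p = 0.00336), while Ccl2 rose. Lipolysis and lipid droplet genes fell for 8 of 18 and rose for 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0307, and adjusted p = 0.574 with an estimated correlation). Among them G0s2, an inhibitor of adipose triglyceride lipase, fell 2.55-fold (adjusted p = 0.00255) and Pde3b, a phosphodiesterase that insulin activates, 1.44-fold (adjusted p = 0.0128). They were 38.5-fold and 20.1-fold lower in the replicate 3 pair. Brown and beige adipocyte genes fell for 4 of 7 (5 adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.447 with an estimated correlation). Cidea fell 5.59-fold, Kcnk3 2.55-fold, Elovl3 2.24-fold and Cox7a1 2.55-fold. Insulin signalling genes fell for 10 of 21 and rose for 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.15). Foxo1 fell 2.15-fold in replicates 1 and 2 and was 1.98-fold lower in the replicate 3 pair (adjusted p = 0.0445 with the processing term). Tbc1d4, a substrate of AKT, fell 1.40-fold (adjusted p = 0.0102), and Socs3, an inhibitor of cytokine signalling, rose 1.83-fold (adjusted p = 0.00402). Relative to all genes, the replicate 3 medians of these 4 lists were −2.05, −3.62, −3.36 and −1.11, each at percentile 0. In the planned fit, camera gave adjusted p = 5.89e-07, 6.09e-10, 2.32e-06 and 0.00447 (adjusted p = 0.153, 0.213, 0.0661 and 0.233 with an estimated correlation).

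The change of mitochondrial genes differed between the 2 kinds of table. Nuclear-encoded respiratory chain genes rose for 9 of 37 and fell for 0 in replicates 1 and 2 (7 and 0 adjusted over the list alone), with a median of 0.32. All 37 were at least 2-fold lower in the replicate 3 pair, with a median of −2.31 relative to all genes, percentile 0. By the interaction test all 37 were more negative in replicate 3. Cox4i1, a subunit of cytochrome c oxidase, was 438 ± 31.8 and 475 ± 52 FPKM (SD, n = 2) in replicates 1 and 2 (adjusted p = 0.523) and 1480 and 284 in the replicate 3 pair. Ndufs3, Ndufs1 and Uqcrc1 were likewise not called in replicates 1 and 2 (adjusted p = 0.838, 0.74 and 0.376) and were 4.65-fold, 3.68-fold and 4.15-fold lower in the replicate 3 pair. Fatty acid oxidation genes rose for 7 of 18 and fell for 0 in replicates 1 and 2 (7 and 0 adjusted over the list alone). Their median was 0.22, against −2.44 relative to all genes in the replicate 3 pair, percentile 0. Acadm, medium-chain acyl-CoA dehydrogenase, rose 1.32-fold (adjusted p = 0.0296) but was 886 in control 3 and 53.7 in CIH 3, while Hadhb and Etfa were not called (adjusted p = 0.803 and 0.523). Camera called both lists up in replicates 1 and 2 (adjusted p = 2.9e-05 and 0.000707; adjusted p = 0.574 and 0.516 with an estimated correlation). It called both down in the planned fit (adjusted p = 2.68e-05 and 0.00478; adjusted p = 0.53 for both with an estimated correlation). The 13 mitochondrial-encoded genes gave 4 higher and 0 lower in replicates 1 and 2 (4 and 0 adjusted over the list alone). Camera gave them adjusted p = 0.00367 there (adjusted p = 0.516 with an estimated correlation) and 0.913 in the planned fit. The gene mt-Nd6 rose 1.81-fold and mt-Nd4l, whose sequence is shared with other genes, 3.04-fold, while mt-Nd5 and mt-Atp8 were not called. In the replicate 3 pair mt-Nd6 was 3976 in control 3 and 2791 in CIH 3, and mt-Nd4l 28611 and 9743. Their median in the replicate 3 pair was −1.76 relative to all genes, percentile 11.5.

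Inflammatory and NF-kB genes rose for 10 of 19 and fell for 3 in replicates 1 and 2 (12 and 5 adjusted over the list alone). Csf1, a growth factor of macrophages, rose 2.43-fold from 4.37 ± 0.648 to 12.0 ± 0.493 FPKM (SD, n = 2; adjusted p = 0.00229) and was 3.95 in control 3 and 53.9 in CIH 3. Haptoglobin, encoded by Hp and abundant in adipocytes, fell from 807 ± 46.9 to 97.4 ± 8.37 FPKM (SD, n = 2; adjusted p = 0.000502) and was 491 and 5.92 in the replicate 3 pair. For inflammation, camera gave adjusted p = 0.000267 in the planned fit (adjusted p = 0.349 with an estimated correlation) and 0.0206 in replicates 1 and 2 (adjusted p = 0.447 with an estimated correlation). The list median was 0.38 in replicates 1 and 2, and 2.06 in the replicate 3 pair where that of all genes was 0.26, percentile 100.

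Interferon response genes went opposite ways in the tables. They fell for 19 of 23 and rose for 0 in replicates 1 and 2 (21 and 0 adjusted over the list alone), with a median of −0.73. Their median in the replicate 3 pair was 2.67 relative to all genes, percentile 100. By the interaction test 22 of 23 were more positive in replicate 3. Ifit3, an antiviral protein, fell from 7.57 ± 0.0932 to 4.19 ± 0.112 FPKM (SD, n = 2; adjusted p = 0.00365) and was 1.10 in control 3 and 61.0 in CIH 3. Mx1 fell 1.35-fold (adjusted p = 0.00946) and Ddx58, the RNA sensor RIG-I, 1.33-fold (adjusted p = 0.0182). They were 24.4-fold and 7.43-fold higher in the replicate 3 pair. Psmb9, an immunoproteasome subunit, was not called (adjusted p = 0.237) and was 0.539 in control 3 and 17.3 in CIH 3. For the interferon list, camera gave adjusted p = 3.25e-09 downward in replicates 1 and 2 (adjusted p = 0.252 with an estimated correlation) and 0.0582 in the planned fit.

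Cell cycle genes rose in replicates 1 and 2 for 25 of 27 members, with 0 lower and 2 not called (25 and 0 adjusted over the list alone). Top2a, a topoisomerase of dividing cells, rose 3.26-fold from 1.97 ± 0.0557 to 8.67 ± 0.421 FPKM (SD, n = 2; adjusted p = 0.000737) and was 1.59 in control 3 and 16.3 in CIH 3. Mcm3 rose 2.54-fold (adjusted p = 0.00128) and Ccnb1, which encodes cyclin B1, 2.34-fold (adjusted p = 0.00137). These were 5.39-fold and 4.11-fold higher in the replicate 3 pair. The list median was 0.99 in replicates 1 and 2 and 1.35 relative to all genes in the replicate 3 pair, percentile 100. For the cell cycle, camera gave adjusted p = 1.17e-24 in the planned fit (adjusted p = 0.0778 with an estimated correlation) and 1.22e-12 in replicates 1 and 2 (adjusted p = 0.252 with an estimated correlation). In the planned fit 17 of the 27 rose adjusted over the list alone and 0 over all genes.

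Replication-dependent histone genes, whose messages lack a poly(A) tail, rose for 6 of 12 and fell for 1 in replicates 1 and 2 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00899, and adjusted p = 0.447 with an estimated correlation). Hist1h4i rose 2.49-fold, Hist1h2bc 2.19-fold and Hist1h1c 1.72-fold, while Hist2h2be fell 1.51-fold (adjusted p = 0.0024, 0.00339, 0.00404 and 0.00428). Hist2h2be was 2.003 in control 3 and 2.037 in CIH 3. Ribosomal protein genes rose for 9 of 32 (0 adjusted over the list alone; camera adjusted p = 0.000201, and adjusted p = 0.574 with an estimated correlation). Rplp0, Rpsa, Rplp1 and Rps3 rose 1.56-fold, 1.66-fold, 1.74-fold and 1.28-fold. The replicate 3 medians of these lists were 1.30 and 0.20 relative to all genes, percentiles 99.9 and 100. In the planned fit camera gave adjusted p = 0.0268 and 0.00765 (adjusted p = 0.591 and 0.659 with an estimated correlation).

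Extracellular matrix genes rose for 14 of 23 and fell for 2 in replicates 1 and 2 (15 and 3 adjusted over the list alone). Sparc, a collagen-binding glycoprotein, rose 2.87-fold from 149 ± 5.95 to 429 ± 29.1 FPKM (SD, n = 2; adjusted p = 0.00123) and was 410.5 in control 3 and 990.1 in CIH 3. Col5a1 rose 2.05-fold (adjusted p = 0.00248), Timp1, an inhibitor of matrix metalloproteinases, 1.76-fold (adjusted p = 0.00469), and Loxl1, a lysyl oxidase, 1.54-fold (adjusted p = 0.00822). Preadipocyte and fibroblast genes rose for 6 of 10 and fell for 3 (6 and 3 adjusted over the list alone), with Thy1 rising 2.49-fold, Vim 1.94-fold and Pdgfrb 1.72-fold. Dlk1, which preadipocytes lose on differentiation, rose from 5.79 ± 0.28 to 9.88 ± 0.218 FPKM (SD, n = 2; adjusted p = 0.00447) and was 9.99 in control 3 and 264.6 in CIH 3. Matrix and preadipocyte medians were 0.54 each in replicates 1 and 2, and 1.91 and 2.50 relative to all genes in the replicate 3 pair, both at percentile 100. Camera gave adjusted p = 0.000223 and 0.0404 in replicates 1 and 2 (adjusted p = 0.516 for both with an estimated correlation), and 1.06e-07 and 0.00356 in the planned fit (adjusted p = 0.349 and 0.517 with an estimated correlation).

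Markers of other cell types were mostly below the filter. Of 10 macrophage markers 2 could be tested, Cd68 and Cd14, and neither was called in replicates 1 and 2 (adjusted p = 0.218 and 0.0935). Cd14 was 1.40 in control 3 and 8.39 in CIH 3. Egfl7, the only endothelial marker past the filter, rose 2.06-fold in replicates 1 and 2 (adjusted p = 0.00757) and was 5.41 in control 3 and 1.69 in CIH 3. Des, the only muscle marker past it, was not called (adjusted p = 0.321). Among bone and cartilage markers Spp1 rose 1.65-fold, Sox9 fell 1.27-fold and Runx2 was not called (adjusted p = 0.00263, 0.0402 and 0.0542). Sox9 and Runx2 were 13.6-fold and 10.3-fold higher in the replicate 3 pair. For these 3 markers camera gave adjusted p = 0.892 in replicates 1 and 2 and 0.0344 in the planned fit (adjusted p = 0.213 with an estimated correlation).

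Over all lists, camera called 21 of 28 in the planned fit, 8 up and 13 down, of which 3 held with an estimated correlation (glycolysis, hypoxia-inducible targets and fatty acid synthesis) and 5 were called by fry. In replicates 1 and 2 alone it called 19, 9 up and 10 down, of which 0 held with an estimated correlation, and fry called 19. With the processing term and an estimated correlation, camera did not call glycolysis, hypoxia-inducible targets or fatty acid synthesis (adjusted p = 0.37, 0.196 and 0.18). Another split of the 6 libraries gave 22 lists in the planned fit, more than the 21 of the real groups.

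**Figure D3:**
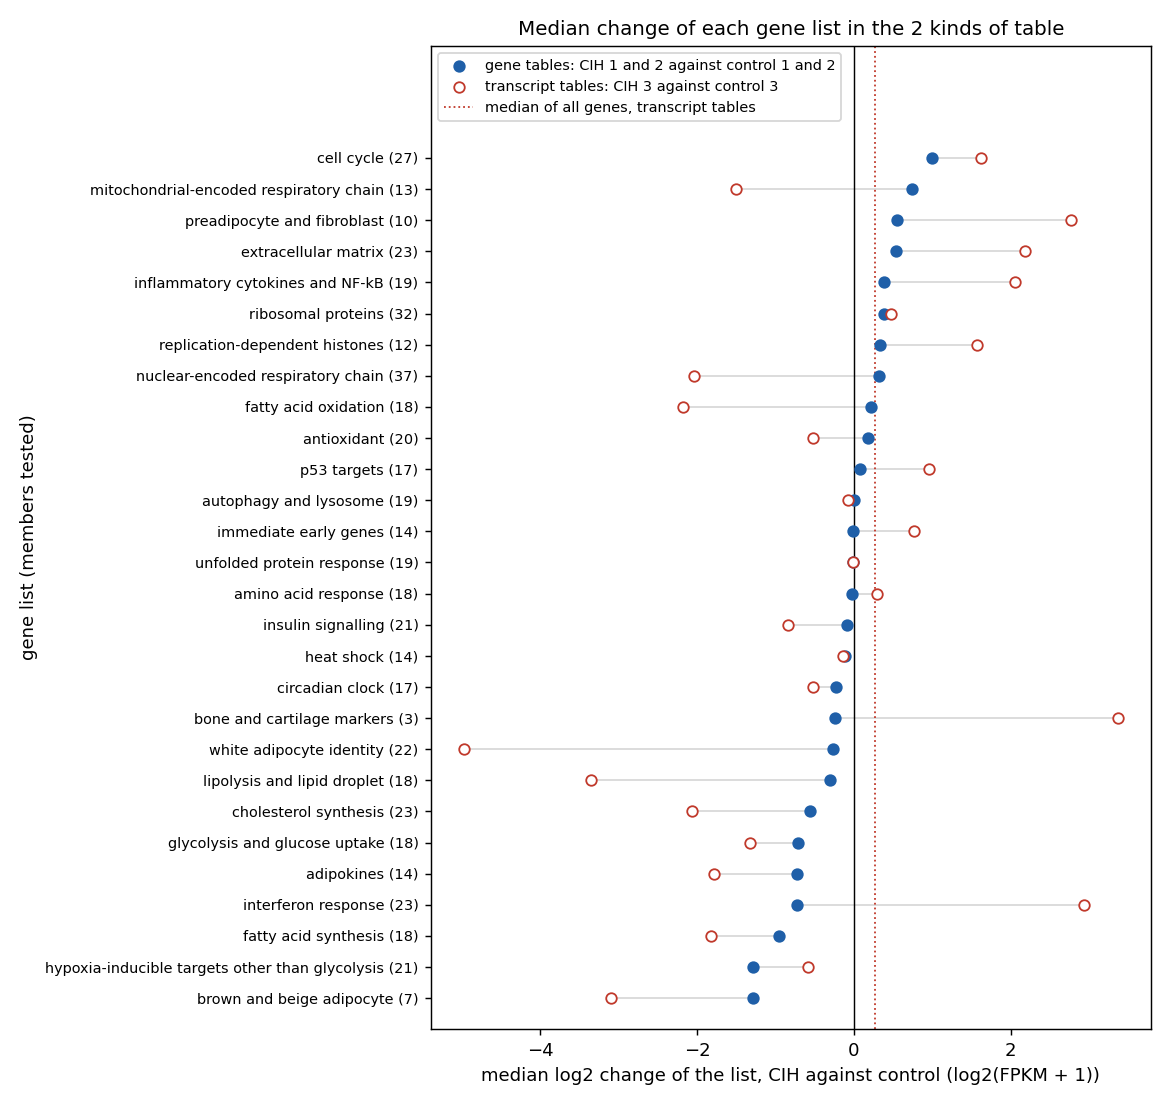
Each line is a gene list with at least 3 tested members (number in parentheses), placed by its median log2 change, CIH against control, in replicates 1 and 2 (filled) and in the replicate 3 pair (open); the dotted line is the median of all genes in the replicate 3 pair (0.26). Cell cycle genes lie to the right and lipid synthesis genes to the left in both, while interferon, respiratory chain and fatty acid oxidation genes lie on opposite sides.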

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

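All tests in this part were chosen after the results were seen. Spread between transcript tables of the same group could not be measured, so the interaction counts rest on that of the gene tables.

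By the interaction of group and kind of table, 7249 of 10976 genes changed differently in the replicate 3 pair than in replicates 1 and 2, 4819 more positive and 2430 more negative; the direction of that balance turned by the median of ratios (2715 and 3760) and with quantile normalization (3608 and 3647). All 22 white adipocyte genes and all 37 nuclear-encoded respiratory chain genes were more negative in replicate 3. More positive there were 22 of 23 interferon genes and 15 of 23 extracellular matrix genes. Calls also came from genes listed only in the gene tables: limma called 48 of 1136 such genes as higher and 31 as lower in CIH. That share is smaller than the 4292 of 10976 called in replicates 1 and 2 among the genes in all files. The 48 higher genes included 8 of 57 small nucleolar RNA genes, and the source of their fragments was not tested. An example chosen after its values were seen is Snord104, at 11.1 and 14.3 FPKM in control 1 and 2 and 27.9 and 27.6 in CIH 1 and 2.

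Genes induced by low oxygen were lower in the libraries named CIH: 15 of 18 glycolytic and 11 of 21 hypoxia-inducible genes, 26 of 39 together, were lower in both kinds of table, while 9 of the 21 were higher in CIH 3. Scaling between the libraries is argued against in replicates 1 and 2, where the upper quartile of the changes of these genes was never above −0.56 over 5 scalings, but stays open in the replicate 3 pair, where it reached 0.97. Of white adipocyte genes, 81.8% lay above the median of the hypoxia-inducible genes in replicates 1 and 2 and 68.2% above that of the glycolytic genes. Most of them thus fell less than the typical gene of either list. Only a cut-off set after the values were seen parts these 2 results. By it, a lower share of adipocytes in CIH 1 and 2 as the whole cause was argued against for the hypoxia-inducible genes alone. White adipocyte genes moved unevenly, since Adipoq was not called while Cfd and Retn fell strongly. Neither result therefore measures the share of adipocytes, and that cause stays open for both lists. Preadipocyte and fibroblast genes (median 0.54) moved with a lower share. An exchange of the control and CIH names for all libraries cannot be told apart from a true fall, because both give the same values and no gene marks the treatment independently. A biological hypothesis, not tested here, is that cells taken in a spell of normal oxygen may have switched these genes off, which harvest at known phases of the oxygen cycle would test.

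Adipocyte genes were lower and interferon genes higher in CIH 3 than in control 3. A gene-specific factor shared by both transcript tables is argued against by the pattern itself, because it would largely cancel between control 3 and CIH 3. Relative to all genes, white adipocyte genes lay at 0.32 in control 3 against control 1 and 2. They lay at −4.97 in CIH 3 against CIH 1 and 2, a difference of −5.29 (interquartile range over the members 2.61). That difference restates how the change of the pair departs from that of replicates 1 and 2, and is no separate test. An exchange of the names of control 3 and CIH 3 cannot be told apart, because the correlation with replicates 1 and 2 was positive (lowest over 5 scalings 0.158) but contrasts that do not part the groups reached 0.171 in size; with the names exchanged, the processing term gave 1 call against 63, 8 lists against 18 and 1760 genes at an unadjusted p under 0.05 against 2052, and 9.93% of genes lay apart against 14.9%. The preadipocyte and fibroblast list lay at percentile 100 of matched random lists. So did the interferon, cell cycle and ribosomal protein lists, and bone and cartilage markers lay at 99.96. That percentile therefore does not single out less adipocyte differentiation in the culture of CIH 3, which stays a possible source. The table holds 1 library per group, so whether that would follow from CIH or from the culture stays open.

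Levels differed between the gene tables and the transcript tables. Fragments shared between genes, counted in the transcript tables and left out of the gene tables, may be a source. The 166 genes with over 90% of their 31-base stretches shared with other genes lay 2.89 (control) and 3.39 (CIH) log2 units higher in the transcript tables, against 0.22 and 0.56 for the 2840 genes sharing none, and the smaller of the differences was 2.67. A gene chosen after its values were seen is mt-Atp8, 204 bases long, which lay 14.1 log2 units higher in control 3. Of its sampled stretches 0% were shared. Only 1 in 8 stretches of annotated transcripts was sampled, so sharing may have been missed. Whether mt-Atp8 is an exception to this source therefore cannot be told. No biological explanation was tested for this pattern.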

How the results depend on the processing

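The fits with the processing term, of replicates 1 and 2 alone and of the interaction, and quantile normalization and voom, were chosen after seeing the data. Count tests of all 6 libraries were not run, because the transcript tables give no whole fragments; their scalings were run on FPKM. For replicates 1 and 2, voom was run on fragments recovered from FPKM and exon length, with library totals. Where a left-out library leaves 1 sample in a group, that sample is assumed to vary like the others. Unless stated, the cause of a change was not tested. Depth limits the precision of low genes in the gene tables, and that of the transcript tables is unknown.

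The planned fit called 0 genes in all alternatives but 1: without control 3 it called 2, both lower (range over left-out libraries 0 to 2 in total, 0 to 2 lower). Its 21 lists went to 3 with an estimated correlation and to 5 with fry. The replicate block ended the 63 calls with the processing term (0, 0 higher, 0 lower), leaving fewer residual degrees of freedom, and changed no other call count by over 1.5 times.

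The 63 calls with the processing term (20 higher, 43 lower) were 0, 0 and 0 with scaling by totals, with no filter and at an adjusted p under 0.01, 270, 118 and 152 by the median of ratios, 183, 92 and 91 by the upper quartile, 114, 47 and 67 with quantile normalization, and 18, 4 and 14 against a fold of 1.2. With the 20 most abundant and the mitochondrial-encoded genes left out, 33 were higher. Over left-out libraries they ranged from 0 to 4274, from 0 to 1979 higher and from 0 to 2300 lower. All 63 genes kept their direction under every setting, and 58 of them were called by the median of ratios, 63 by the upper quartile and 47 with quantile normalization. The 18 lists of that fit went to 0 with an estimated correlation and to 7 with fry.

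Replicates 1 and 2 alone gave 4292 calls (1995 higher, 2297 lower), 2584, 1129 and 1455 with no filter, 1404, 599 and 805 against a fold of 1.2, 1740, 745 and 995 at an adjusted p under 0.01, and 435, 158 and 277 of at least 2-fold. With voom, 5296 of 10897 genes were called, 2424 higher and 2872 lower, among them 4181 of the 4292 in the same direction. Over left-out libraries they ranged from 1865 to 3682, from 827 to 1736 higher and from 1038 to 1946 lower, lowest without CIH 1 and next without CIH 2 (2316, 1124 and 1192). Their 19 lists went to 0 with an estimated correlation. The interaction's 4819 and 2430 were 8054 and 1135 with scaling by totals, 2715 and 3760 by the median of ratios, and 3608 and 3647 with quantile normalization, so the balance turned under both; at least 2-fold, 3910 differed, 2614 and 1296.

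Of values for named genes with the processing term, 135 kept direction and call, 8 became calls and 177 lost theirs. For those in replicates 1 and 2 the numbers were 668, 2 and 85, and 13 reversed, all of genes without a call. With scaling by totals these were Etfa (−0.0407), Ndufs3 (−0.081), Ndufs1 (−0.0762), Cox4i1 (−0.00382), Uqcrc1 (−0.000286) and mt-Atp8 (−0.0994). Over left-out libraries, Hadhb ranged from −0.122 to 0.056, Ndufs3 from −0.10 to 0.172, Ndufs1 from −0.0492 to 0.129 and mt-Atp8 from −0.213 to 0.232. Hif1a in the planned fit, without a call, ranged from −0.115 without CIH 3 to 0.985 without control 3.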

Other observations

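Tests of the planned fit and the splits below were planned; those of replicates 1 and 2 alone and of the processing term were chosen after the result was seen.

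Genes of the circadian clock fell for 8 of 17 members and rose for 2 in replicates 1 and 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0315, and adjusted p = 0.516 with an estimated correlation). Rora, a nuclear receptor, fell 2.81-fold and was 2.47-fold lower in the replicate 3 pair (limma adjusted p = 0.0396 with the processing term). Bhlhe40, a repressor that hypoxia also induces, fell 6.10-fold in replicates 1 and 2 (adjusted p = 0.000392) but was 8.86 in control 3 and 11.6 in CIH 3. Per1 fell 1.36-fold (adjusted p = 0.0191). The list lay at −0.78 relative to all genes in the replicate 3 pair, percentile 0.01, and its own median there was −0.52, or 0.04 with scaling by totals. Camera gave adjusted p = 0.00163 in the planned fit (adjusted p = 0.213 with an estimated correlation).

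Stress lists went both ways. Of 17 p53 targets, 8 rose and 3 fell in replicates 1 and 2 (8 and 3 adjusted over the list alone; camera adjusted p = 0.142; planned fit 0.0448, and adjusted p = 0.592 with an estimated correlation). Trp53 rose 1.77-fold, Plk2 1.86-fold and Bax 1.54-fold, while Btg2, an antiproliferative gene, fell 2.09-fold and was 2.64-fold lower in the replicate 3 pair (adjusted p = 0.0484 with the processing term). Of 20 antioxidant genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.148), with Nqo1 rising 1.91-fold and Tkt, transketolase, falling 2.08-fold. Of 19 unfolded protein response genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.259; planned fit 0.0439, and adjusted p = 0.213 with an estimated correlation). Ddit3 rose 1.52-fold, and Xbp1 fell 1.62-fold. Of 18 ATF4 targets, 5 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.725). Atf5 rose 1.43-fold and Chac1 fell 1.90-fold. Of 14 immediate early genes, 6 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.649), with Fos rising 2.85-fold and Egr1 1.78-fold. Autophagy and heat shock lists had camera adjusted p = 0.498 and 0.592, with Gabarapl1 falling 1.73-fold and Dnajb1 1.34-fold in replicates 1 and 2. Gabarapl1 was 181.6 in control 3 and 201.2 in CIH 3.

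The 6 libraries split in 10 ways into groups of 3, too few for a share under 0.05. In the planned fit, all 10 splits gave as many called genes as the real groups (0, highest other 0), and 2 of 10 as many lists (21, highest other 22, from control 1, control 3 and CIH 2 against the rest). With the processing term, 1 of 10 gave as many called genes (63, highest other 1) and 5 of 10 as many lists (18, highest other 21). Of these splits, 4 part all 3 pairs of replicate numbers, and with the processing term these called 63 (the real groups), 1, 0 and 0 genes. At an unadjusted p under 0.05 they had 2052, 1760, 9 and 21, so the split that exchanges control 3 and CIH 3 came close to the real groups by that count. Splits that put both transcript tables in the same group had 927 to 1530 genes at an unadjusted p under 0.05 in the planned fit, against 490 for the real groups, which points to the kind of table as a structure of the libraries. Within the gene tables alone, the real groups gave 4292 calls and the other splits of 2 against 2 gave 0 and 0. Those splits put 1 control and 1 CIH library on each side, so a group difference adds to their spread. By limma they had 26 and 33 genes at an unadjusted p under 0.05, so their 0 calls set no chance level for the 4292. The same limit holds for the 0 and 0 calls above, from the splits that exchange pair 2 or pair 1.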
